A study of Macaca fascicularis and Mus musculus with 492 samples.

How the data were processed

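SC3-seq libraries of single cells were analysed, 421 from cynomolgus monkey and 71 from mouse, each deposited as 1 sample. The deposited tables hold RPM per gene and cell, made by the authors. Per the submitters' processing notes, cutadapt 1.3, TopHat 1.4.1 and Cufflinks 2.2.0 were used, with no role given for each, and the notes name the build mm10. Per the file headers, the monkey genes refer to the build macFas5 and the mouse genes to mm10. Filters, spike-ins and the assignment of reads to genes are not given in the sources used here.

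The monkey table has 29095 genes, of which 298 hold no value in any cell, and 28797 were used. The mouse table has 26219 genes and 108 columns of values, of which 37 match no sample here and were not used. Of 14758 monkey genes with a LOC name, 3296 were given a symbol from a reference gene table by their gene ID. In each cell the most common value above 0.01 RPM was taken as the step of 1 read, and reads were recovered as the deposited RPM over that step. In every cell at least 99.6017% of values above 0.01 RPM and under 500 steps lay within 0.1 of a whole read. Monkey cells had 7799 to 13302 genes detected (median 10986) and mouse cells 9297 to 15223 (median 10912). Molecular identifiers are not given in the sources used here. Intervals (95%, exact Clopper-Pearson) and the limits for a share of 0 (3 cells of the total) cover counting error only. No cell was removed. The cells were picked singly, no doublet caller was run, and no 2 cells had a correlation above 0.9477 in monkey or 0.9223 in mouse.

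Cell classes were rebuilt, since the sources used here give none. Embryo cells of each species were clustered on log2(RPM + 1) of the 2000 most variable genes (above 10 RPM in at least 5 cells) with scanpy 1.11.5 and igraph 0.11.9, by 12 principal components and 10 neighbours (8 and 8 in mouse) and Leiden resolution 1 (1.5 as the alternative). A cluster was called X-like when more than 50% of the detected markers of 1 class, and at least 3, were above the other cells by at least 1 (log2) with a cluster mean of at least 3, with no other class at the same share. It stayed unnamed when another class had more markers among its 10 leading genes. This naming rule, its threshold and the clustering settings were set after monkey clusters at resolutions 0.5, 1, 1.5 and 2 and mean marker levels had been seen. The unnamed clusters 7 (E06) and 9 (E13 and E14) had 4 of 8 epiblast markers elevated, exactly at the threshold, so the rule decided that E06, planned as an early day, was left out. Recollection of how the published study of these data classes E06 cells entered that decision, so it was not blind to that study, and the comparison was also run with each of the 2 clusters counted as epiblast-like. Epiblast markers of monkey were POU5F1, NANOG, SOX2, PRDM14, GDF3, DPPA4, L1TD1 and SALL4, most of which are also in the core pluripotency list.

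The labels name no embryos and number the cells, so cells were not treated as replicates. For each class and day, or ESC culture, the mean of log2(RPM + 1) over cells was the unit, units of under 5 cells were left out, and genes with a unit mean of at least 2 in at least 3 units were tested. Late (E13, E14, E16, E17) against early (E07, E08, E09) epiblast-like days, the 3 monkey ESC cultures against late and against early days, and the trend of trophectoderm-like cells over E06 to E09 were fitted with limma 3.58.1 (lmFit, eBayes with an intensity trend) in R 4.3.3. Adjusted p is Benjamini-Hochberg over all tested genes of a comparison, with a threshold of 0.05, and all tests are two-sided. The 3 ESC cultures come from 2 lines, so 2 of them are not fully independent, and p measures the spread between days or cultures, not between animals. The planned comparison of late with early endoderm-like cells could not be run, since no late day held such cells. The tests, the groups, the gene lists, the markers and the rule for named genes were chosen before the data were examined, but not the rule that turns markers into names.

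Gene lists covered core, preimplantation (naive) and postimplantation (primed) pluripotency, DNA methylation, chromatin and histone modifiers, FGF and ERK, NODAL and activin, WNT, BMP, and JAK-STAT and LIF signalling, gastrulation, glycolysis, oxidative phosphorylation, the cell cycle, apoptosis and p53 targets, adhesion and extracellular matrix, dissociation stress and neural genes. Lists of markers of other cells covered trophectoderm, hypoblast and endoderm, extraembryonic mesenchyme, amnion, germ cells, blood and immune cells, trophoblast hormones and placental genes, and apolipoproteins and lipid transport. Lists with at least 4 tested members were tested with camera (preset correlation 0.01, and an estimated one beside it), adjusted over the lists. Camera compares a list with all other tested genes. All of its calls were lost with an estimated correlation. Named genes were the 10 largest rises and 10 largest falls among genes past the threshold with a change of at least 1, no overlap between the groups (for the trend, 1 direction at each step), a mean of at least 3 in the higher group and a symbol that does not start with LOC, and up to 4 tested members of each list by size of change. Fewer are printed.

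ESC cultures among themselves and all mouse groups are 1 sample each, so no test was made. Differences of mean log2(RPM + 1) are given with the SD over cells, and named genes had a mean of at least 3 in the higher group and were detected in at least 75% of its cells. Medians of lists are given with their percentile among 10000 random lists of the same size, matched on expression in 20 bins. Genes with a mean of at least 2 in either group entered. Profile similarity is the Pearson correlation across the 2000 most variable tested genes. Monkey and mouse changes were computed within each table and matched by symbol without regard to case.

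The limma, edgeR and camera steps were tested on simulated data of the same design, with 100 genes changed by 1 and 100 by 2 (log2). Each gene was drawn independently, so the simulation could not check the correlation between genes that camera assumes. Limma recovered 11 and 63 of them for late against early epiblast, 11 and 58 for ESCs against late days, 7 and 33 for ESCs against early days, and 61 and 86 for the trend (per day). Its calls included 4 of 78, 6 of 75, 3 of 43 and 3 of 150 unchanged genes. EdgeR recovered 4 and 48, 0 and 70, 3 and 40, and 53 and 100 in the same order, and called 1, 4, 2 and 6 unchanged genes. With so few changed genes, changes of 1 between groups were mostly missed in the simulation. The data had many more calls, 3752 for late against early epiblast, of which 3030 changed by at least 1. Recovery at that number of changed genes was not simulated.

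Alternatives were pseudocounts of 10 and 0.1 in place of 1, no filter and a stricter one (4), log2 of the mean RPM, quantile normalization, each day or culture left out, at least 10 cells per unit, the same number of cells per unit, units split by day and title code (at least 3 cells) with the day as a random block, the higher clustering resolution, edgeR 4.0.16 (quasi-likelihood) on summed recovered reads, eBayes without a trend, and 1 fit with 3 groups. The title code is MS and a number in each sample's name, and its meaning is not given in the sources used here. Thinning each cell to the same number of reads (293673 for late against early epiblast), counting the unnamed clusters as epiblast-like, the comparison within the title code MS11, and leaving out E6.5 cells with Igkc above 1000 RPM were added after the data had been seen. So were the test of other cells on the called falls and tests on genes called without the cells tested: late against early epiblast without cells of MS08, ESCs against late days without those of MS11 (units of under 5 cells left out) and without the feeder-free culture, with the called genes then read in the cells left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.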

Results

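RNA was measured in single cells by SC3-seq, a method that amplifies the cDNA of 1 cell and sequences the 3-prime ends of transcripts. The samples were 390 cells of cynomolgus monkey embryos, 31 cells of monkey embryonic stem cells (ESCs), 49 cells of mouse embryos, 10 mouse ESCs grown in 2i and LIF, and 12 mouse epiblast-like cells (EpiLCs). The monkey embryos gave 43 cells at embryonic day 6 (E06), 35 at E07, 95 at E08, 20 at E09, 46 at E13, 62 at E14, 36 at E16 and 53 at E17. The monkey ESCs were the line CMK6 on feeder cells (14 cells), CMK6 without feeders (9 cells) and CMK9 on feeders (8 cells). The mouse embryos gave 25 cells at E5.5 and 24 cells at E6.5. The deposited values are in RPM, and each monkey cell had a median of 1879342 recovered reads (166742 to 4491539). Each mouse cell had a median of 2642943 recovered reads (1004103 to 4158784). Among the monkey days, E17 was the shallowest, with a median of 912193 reads per cell, and E09 the deepest of the embryo days, with 2049967. The labels name no embryos, so the unit of replication was the embryonic day or the ESC culture, and the spread below is that between days or cultures.

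The first question was which cell classes each day held. At E07 to E09 the monkey embryos held cells with the markers of epiblast (the future embryo proper), hypoblast (the primitive endoderm) and trophectoderm (the future placenta). Of the E08 cells, 25.3% (24 of 95; 95% Clopper-Pearson interval 16.9% to 35.2%) were epiblast-like, 38.9% (29.1% to 49.5%) hypoblast-like or endoderm-like and 35.8% (26.2% to 46.3%) trophectoderm-like. At E07 the epiblast-like share was 14.3% (4.81% to 30.3%) and the trophectoderm-like share 54.3% (36.7% to 71.2%), and at E09 they were 25% (8.66% to 49.1%) and 40% (19.1% to 64%). The hypoblast-like or endoderm-like share was 28.6% (14.6% to 46.3%) at E07 and 35% (15.4% to 59.2%) at E09. At E06, 27.9% of cells (12 of 43; 15.3% to 43.7%) were trophectoderm-like and 31 cells fell in a cluster left unnamed, led by DPRX, SPIC, NLRP7 and KLF4. None of the 43 E06 cells was called epiblast-like, which allows a share of up to 6.98%, but 46.5% were with a higher clustering resolution.

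From E13 on, cells with the markers of extraembryonic mesenchyme (COL3A1, LUM and DCN, genes of extracellular matrix) and of gastrulation (LHX1, EOMES and CER1) were present, the first up to E16. The extraembryonic-mesenchyme-like share was 34.8% (16 of 46; 21.3% to 50.3%) at E13, 22.6% (12.9% to 35%) at E14 and 5.56% (2 of 36; 0.68% to 18.7%) at E16, and none of the 53 E17 cells had it (share of up to 5.66%). The gastrulating-like share was 4.35% (2 of 46; 0.531% to 14.8%) at E13, 1.61% (1 of 62; 0.0408% to 8.66%) at E14, 30.6% (16.4% to 48.1%) at E16 and 37.7% (24.8% to 52.1%) at E17. These shares leave out the unnamed cluster 9, led by SPP1, T and HAS2, with 4 cells at E13 and 13 at E14. It had 4 of 9 gastrulating markers elevated, T, MIXL1, EOMES and SP5, beside 4 of 8 epiblast markers. The epiblast-like share was 52.2% (36.9% to 67.1%) at E13, 40.3% (28.1% to 53.5%) at E14, 58.3% (40.8% to 74.5%) at E16 and 62.3% (47.9% to 75.2%) at E17. Trophectoderm-like cells made up 14.5% of E14 cells (9 of 62; 6.86% to 25.8%). No hypoblast-like or endoderm-like cell was found among the 46 cells of E13 or the 53 of E17, which allows shares of up to 6.52% and 5.66%. The gastrulating-like cluster had 5 of 10 hypoblast and endoderm markers elevated, GATA4, GATA6, SOX17, PDGFRA and FOXA2. In the mouse, 64% of E5.5 cells (16 of 25; 42.5% to 82%) were epiblast-like and 36% (18% to 57.5%) visceral-endoderm-like, visceral endoderm being the extraembryonic layer around the epiblast. At E6.5 these shares were 37.5% (9 of 24; 18.8% to 59.4%) and 20.8% (7.13% to 42.4%), and 10 cells led by T, Mesp1 and Sp5 stayed unnamed. Each day is 1 sample, and no shares were tested between days. Intervals and limits cover counting error only.

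**Figure D1:**
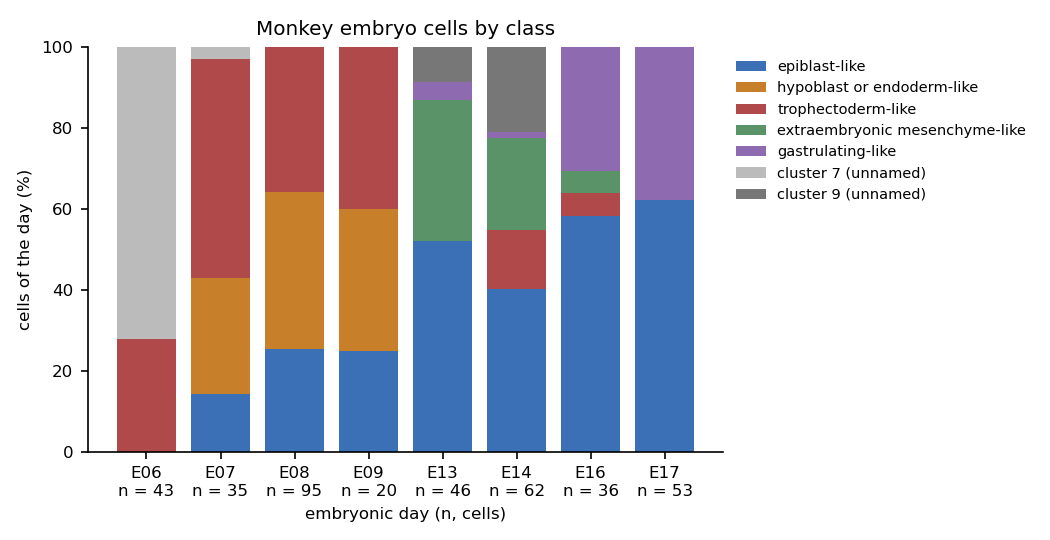
Share of cells of each class (percent of the day's cells) by embryonic day in monkey embryos, with the number of cells of each day under its bar. Hypoblast-like cells were found at E07 to E09 and gastrulating-like cells from E13 on.

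The next question was how epiblast-like cells differed between early (E07 to E09) and late (E13 to E17) days. Secreted WNT antagonists and a cyclin were among the largest rises, and KHDC1L and NLRP genes among the largest falls. SFRP1 (gene ID 102133214), a secreted WNT antagonist, rose from a mean log2(RPM + 1) of 2.02 to 8.74, by 6.72 ± 0.64 (SE, 3 early and 4 late days). CD24 (gene ID 101867055), a surface glycoprotein, rose by 6.08 ± 0.28 and CCND2, a cyclin of the G1 phase, by 6.16 ± 0.38. KHDC1L fell by 9.37 ± 0.47 and NLRP7, a gene of the maternal-effect NLRP family, by 8.37 ± 1.29. S100P, a calcium-binding protein, changed by -9.36 ± 0.45. The adjusted p was 1.13e-05 for SFRP1, 7.52e-08 for CD24, 8.87e-08 for KHDC1L and 0.000378 for NLRP7.

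In all, 3752 of 9876 tested genes passed the limma test between early and late epiblast-like days, 1309 higher and 2443 lower on the late days, and 3030 of them changed by at least 1. The groups did not overlap for 4262 genes, or 43.2% against 5.71% by chance. Higher genes were 34.9% of those called as deposited, 51.7% after quantile normalization and 48.9% with the log of the mean RPM, so the balance of rises and falls depends on the scaling. The median change of all tested genes was -0.27, and -0.01 after quantile normalization. Other leading rises were SFRP2 (6.37 ± 0.45), NREP (6.30 ± 0.34), the matrix proteoglycan VCAN (6.30 ± 0.49) and CRABP2, which binds retinoic acid (5.39 ± 0.51). Other leading falls were ANXA8 (-7.97 ± 0.37), the homeobox gene DPRX (-7.29), NLRP9 (-7.20) and OOEP (-6.64 ± 1.14), an oocyte-expressed gene. How reads shared between members of a gene family were assigned is not given in the sources used here, so values of the KHDC and NLRP families (among them KHDC1L, KHDC3L, OOEP, NLRP2, NLRP7 and NLRP9) are uncertain in that respect. The early cells came from cluster 6, those of E13 and E14 from cluster 4 and those of E16 and E17 from cluster 1. E06 was planned as an early day, but the cluster that held its epiblast-marker cells had 4 of 8 epiblast markers elevated and missed a name under a threshold set after the clusters were seen. With that cluster counted as epiblast-like, 4018 genes were called.

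The preimplantation (naive) list, transcription factors and other genes typical of blastocyst epiblast, had 11 of 14 tested members fall and 1 rise (the same counts adjusted over the list alone). DNMT3L, a cofactor of de novo DNA methylation, fell by 5.90 ± 1.13, and the transcription factors SOX15 by 5.64 and TFCP2L1 by 5.59 ± 0.39. Its median was -3.41 relative to all genes, and camera called it lower (adjusted p = 0.000201; adjusted p = 0.387 with an estimated correlation). The postimplantation (primed) list had 10 of 12 members rise and 0 fall (11 and 0 adjusted over the list alone). Its largest rises beyond the SFRP genes were those of SOX11, a neural and epiblast transcription factor, by 5.03 ± 0.38 and of the growth factor FGF2 by 3.77 ± 0.38. Its median was 2.53 relative to all genes (camera adjusted p = 1.36e-08; adjusted p = 0.225 with an estimated correlation). The core pluripotency list, which shares most members with the epiblast markers, had 3 of 10 members rise and 5 fall (3 and 5 adjusted over the list alone). NANOG fell by 1.99 ± 0.25, DPPA4 by 1.71 and GDF3, a TGF-beta family ligand, by 1.38, and the RNA-binding protein gene LIN28B rose by 1.3. Its camera adjusted p was 0.624.

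Among signalling lists, NODAL and activin had 5 of 8 members fall and 1 rise (5 and 1 adjusted over the list alone). The ligand NODAL fell by 4.44 ± 0.36, its inhibitor LEFTY1 by 4.73 ± 0.41, the signal transducer SMAD3 by 2.70 and its inhibitor SMAD7 by 2.51 (camera adjusted p = 0.0831). BMP signalling had 4 of 10 members rise and 0 fall (5 and 1 adjusted over the list alone), with ID3, a direct BMP target, at 3.16 ± 0.63, BAMBI at 2.44 and the ligand BMP4 at 2.13. Camera called it higher (adjusted p = 0.0402; adjusted p = 0.67 with an estimated correlation). WNT signalling had 4 of 7 members rise and 1 fall, with the same counts adjusted over the list alone. Those that rose included the antagonists SFRP1 and SFRP2 and the receptor FZD7 (2.06), and the WNT target AXIN2 fell by 2.53. Camera called the WNT list higher (adjusted p = 0.0475; adjusted p = 0.372 with an estimated correlation), but not after quantile normalization (adjusted p = 0.0652). FGF and ERK signalling had 2 of 11 members rise and 2 fall, both counts the same adjusted over the list alone, with FGF4 at -2.53 and FGFR2 at 1.86 (camera adjusted p = 0.237). JAK-STAT and LIF signalling had 1 of 7 members rise and 2 fall (1 and 4 adjusted over the list alone), with the co-receptor IL6ST at -2.87 and the LIF receptor LIFR at 1.99 (camera adjusted p = 0.355).

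In metabolism, glycolysis had 10 of 18 members rise and 2 fall (10 and 2 adjusted over the list alone), led by PKM (3.0), ALDOC (2.33), PFKP (2.10) and TPI1 (2.06). Camera called it higher (adjusted p = 0.00563; adjusted p = 0.555 with an estimated correlation). The median of the glycolysis list was 6.69, 7.03 and 7.21 at E07, E08 and E09. It was 7.59, 7.70 and 7.52 at E13, E14 and E16, but 6.78 at E17, within the range of the early days. Oxidative phosphorylation had 1 of 18 members rise and 5 fall (1 and 5 adjusted over the list alone), among them COX5A by 1.89 and COX6C by 1.72 (camera adjusted p = 0.198). DNA methylation had 3 of 9 members rise and 3 fall (4 and 3 adjusted over the list alone), with DNMT1, the maintenance methyltransferase, at 2.37 and TET2, a demethylating enzyme, at -2.81. Chromatin modifiers had 0 of 16 members rise and 4 fall (0 and 4 adjusted over the list alone), with the Polycomb genes SUZ12 at -1.72 and EED at -1.32. The cell cycle list had 3 of 17 members rise and 6 fall (3 and 6 adjusted over the list alone), with CCND1 at 4.43 and CCND3 at -2.24. The apoptosis list had 2 of 8 members rise and 5 fall (2 and 5 adjusted over the list alone), with the p53 target BBC3 at -3.65. Adhesion and extracellular matrix had 3 of 14 rise and 7 fall (4 and 7 adjusted over the list alone), with the intermediate filament VIM at 3.4 and the laminin LAMC1 at -2.62. Camera adjusted p was 0.546 for DNA methylation, 0.998 for chromatin, 0.868 for the cell cycle, 0.546 for apoptosis and 0.968 for adhesion. Median and mean differed in sign for DNA methylation (0.09 and -0.52), chromatin (0.03 and -0.26, with camera's direction down) and the cell cycle (-0.39 and 0.22, with camera's direction down).

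Of markers of other cell types, trophectoderm had 0 of 5 members rise and 3 fall (0 and 4 adjusted over the list alone), namely TFAP2C by 6.11 ± 0.40, KRT18 by 4.89 and GATA2 by 2.35. Camera called the trophectoderm list lower (adjusted p = 0.0194; adjusted p = 0.372 with an estimated correlation). Germ cell markers had 0 of 4 rise and 3 fall, including KIT by 2.14 (camera adjusted p = 0.0831), and gastrulation genes 0 of 4 and 3, including CDX1 by 4.08 (camera adjusted p = 0.101). MIXL1, in the gastrulation list, was at -2.20 but at 0.24 with edgeR. Hypoblast and endoderm markers had 2 of 6 rise and 2 fall, with the secreted protein AFP at 2.14 and the nuclear receptor HNF4A at -3.98 (camera adjusted p = 0.947; median 0.16, mean -0.24). Extraembryonic mesenchyme markers had 2 of 5 rise, COL1A1 (2.94) and BST2 (1.56), and 0 fall (camera adjusted p = 0.237). Trophoblast hormones and placental genes had 2 of 4 rise and 2 fall (camera adjusted p = 0.546), with HSD11B2 at 3.27 and GCM1 at -3.13. These 5 lists had the same counts adjusted over the list alone. Of lists with under 4 tested members, the neural gene NES rose by 2.18, the amnion marker HEY1 fell by 1.99, 1 of 3 apolipoprotein and lipid transport genes rose (MTTP, 1.4) and no blood or immune marker was expressed highly enough to be tested. Dissociation stress genes had 0 of 9 rise and 3 fall (0 and 3 adjusted over the list alone), with DNAJB1 at -1.74 and IER2 at -1.43 (camera adjusted p = 0.546). Keeping only days with at least 10 cells, which leaves E08 as the only early day, gave 763 calls, and the same number of cells per day gave 2150. GATA6, a hypoblast gene that fell by 1.76, was at 0.08 within the title code MS08, which holds late cells and only 2 early ones.

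**Figure D2:**
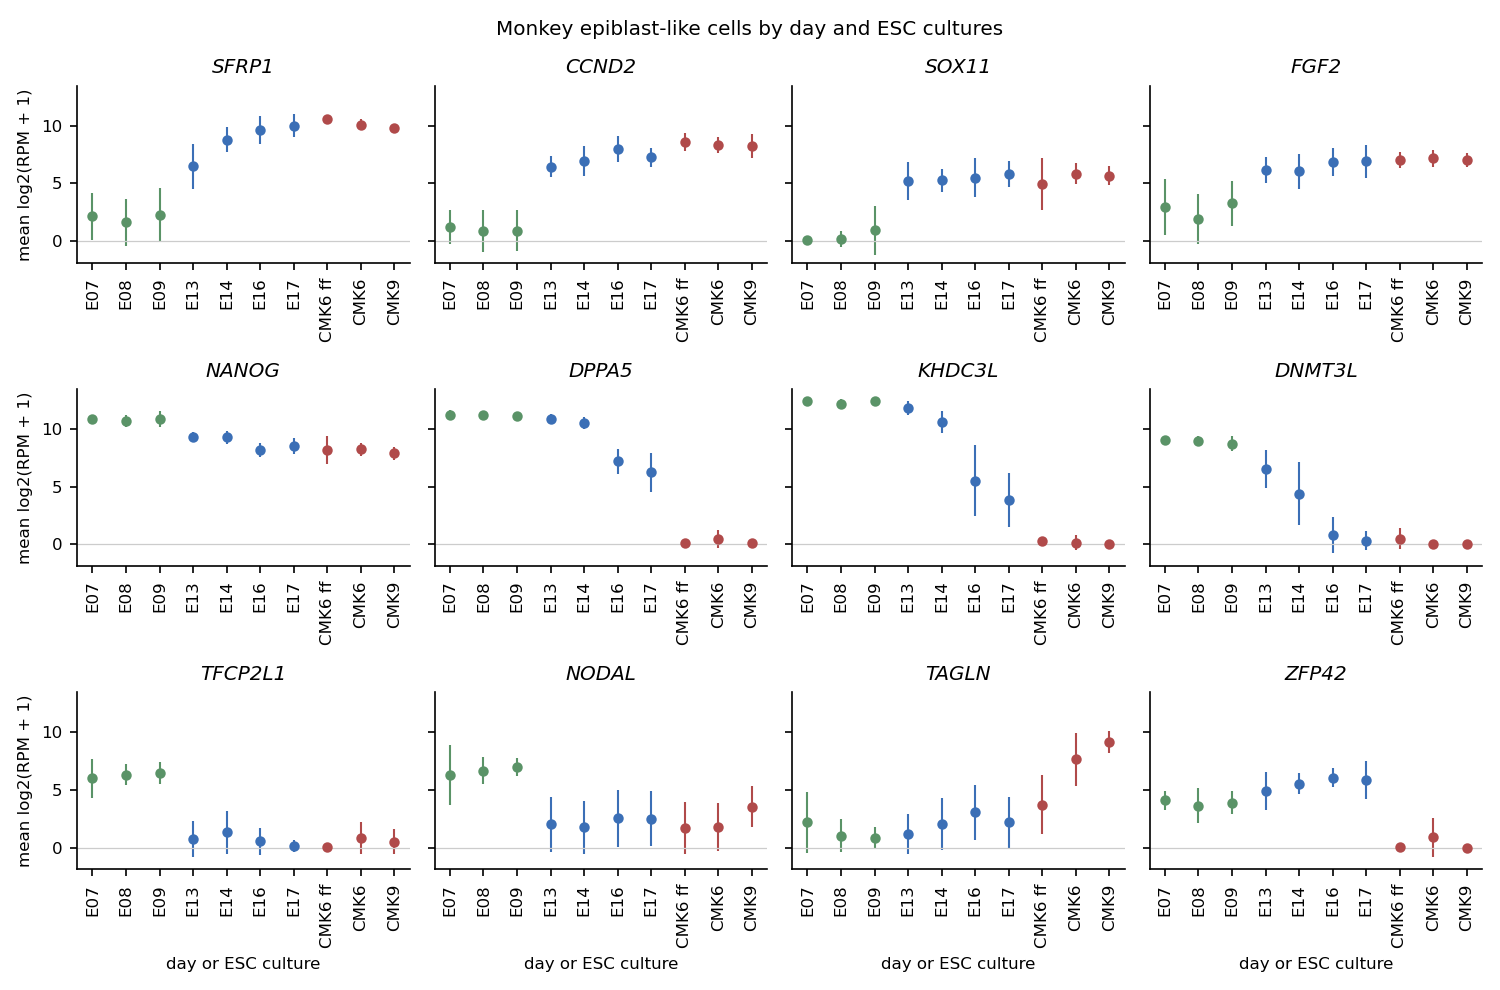
Mean log2(RPM + 1) of 12 genes in epiblast-like cells by embryonic day and in the 3 monkey ESC cultures, with bars for the SD over cells. SFRP1 ran from 1.62 at E08 to 10.01 at E17, and DPPA5 stood at 6.25 at E17 and at or below 0.47 in the ESC cultures.

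Monkey ESCs were compared with late epiblast-like cells, which lay nearer to them in profile than early ones did. DPPA5 and ZFP42 were near 0 in ESCs, and TAGLN and SLC7A11 were among the largest rises. DPPA5, an RNA-binding protein of pluripotent cells, fell by 8.50 ± 0.95 (SE, 3 cultures and 4 days), and ZFP42, a zinc finger gene of the naive list, fell by 5.28 ± 0.42, from 5.59 to 0.31. In early epiblast-like cells ZFP42 stood at 4.10, 3.64 and 3.89 (E07, E08 and E09), below its late mean. KHDC3L, an oocyte and embryo gene, fell by 7.79 ± 1.54 and the zinc finger gene ZNF208 by 7.74 ± 0.50. TAGLN, an actin-binding protein, rose by 4.72 ± 0.99, and SLC7A11, a cystine transporter, by 4.27 ± 0.54. Adjusted p was 0.00145 for DPPA5, 0.000101 for ZFP42, 0.0145 for KHDC3L, 0.0171 for TAGLN and 0.00263 for SLC7A11.

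Of 9865 genes, 888 passed the limma test between ESC cultures and late epiblast-like days, 741 higher and 147 lower in ESCs, and 782 changed by at least 1. The groups did not overlap for 2400 genes, or 24.3% against 5.71% by chance. Higher genes were 83.4% of the calls as deposited, 55.6% after quantile normalization and 67.5% with the log of the mean RPM. The median change of all genes was 0.29, and -0.02 after quantile normalization. Other leading rises were PCDHAC2, a protocadherin (3.95 ± 0.32), PHLDA1 (3.95 ± 0.44), the transcription factor KLF10 (3.74), the protease PLAU (3.71) and the smooth muscle gene CNN1 (3.71). For TAGLN the feeder-free culture was at 3.71, CMK6 on feeder at 7.65 and CMK9 at 9.15, against a mean of 2.12 over the late days. Other leading falls were NLRP2 (-6.00), TRIM60 (-5.20), REC8, a meiotic cohesin (-5.17 ± 0.47), and GDF3 (-4.25 ± 0.39). TRIM60 stood at 2.04 at E17 and between 6.03 and 6.76 on the other late days, and was at 0.25 between the feeder-free ESCs and E17 cells within the title code MS11.

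The naive list had 3 of 7 members fall, DPPA5, ZFP42 and FGF4 (-2.87), and 0 rise (4 and 1 adjusted over the list alone). Its median was -3.16 relative to all genes, and camera called it lower (adjusted p = 6.14e-05; adjusted p = 0.482 with an estimated correlation). It was the only list that camera still called after quantile normalization (adjusted p = 0.00452). Only 7 members were tested, beside 14 in late against early epiblast, whose median was 0.22 to 0.94 in the ESC cultures. A member near 0 in ESCs entered only by reaching 2 on at least 3 late days, and could then only fall. The list's direction thus follows in part from the filter. The core list had 1 of 10 fall, GDF3, and 0 rise (2 and 0 adjusted over the list alone), with NANOG at -0.72 (adjusted p = 0.11) and SOX2 at 0.89. Camera placed it below other genes (adjusted p = 0.0434; adjusted p = 0.523 with an estimated correlation). It did the same for BMP signalling (adjusted p = 0.0434; adjusted p = 0.523 with an estimated correlation), where 0 of 9 members passed the limma test (1 lower at an unadjusted p under 0.05 and adjusted over the list alone, 0 with edgeR) and BAMBI stood at -1.31. Glycolysis had 2 of 18 fall, LDHA by 2.05 and HK2 by 1.37, and 0 rise (3 and 0 adjusted over the list alone; camera adjusted p = 0.0196; adjusted p = 0.523 with an estimated correlation). The cell cycle list had 1 of 17 rise, CCND2 by 1.24, and 1 fall, the checkpoint kinase BUB1 by 0.98 (camera adjusted p = 0.0434; adjusted p = 0.482 with an estimated correlation).

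The primed list had 3 of 15 members rise, the surface protein THY1 (2.42), CRABP1 (2.02) and FZD7 (1.96), and 0 fall (camera adjusted p = 0.276). CRABP1 was at -0.81 and HK2 at 0.84 within the title code MS11. FGF and ERK signalling had 2 of 11 rise, the ERK phosphatase DUSP6 (3.51) and SPRED1 (1.79), and 1 fall, FGF4 (camera adjusted p = 0.207). Adhesion had 3 of 16 rise, including the laminin LAMB1 (2.47), and 0 fall (5 and 0 adjusted over the list alone). DNA methylation had GADD45A at 3.18 and TET1 at -0.91 as its only calls among 8 members, and its median (-0.09) and mean (0.12) differed in sign. NODAL and activin had 1 of 6 fall, GDF3 (median 0.11, mean -0.50). The limma test passed 0 of 15 chromatin modifiers, 0 of 6 JAK-STAT and LIF genes and 0 of 9 dissociation stress genes. At an unadjusted p under 0.05 these lists had 3, 2 and 4 genes, and edgeR passed 0, 0 and 1. Of markers of other cell types, the keratin KRT18 (1.78), the collagen COL1A1 (1.52), the amnion gene VTCN1 (2.96) and NES (1.51) rose. Leaving out 1 culture gave 168 calls without CMK6 on feeder, 151 without CMK9 and 634 without the feeder-free one, and leaving out E14 gave 361. With quantile normalization 441 genes were called, with edgeR 364, and with at least 10 cells per unit, which leaves 1 culture, 13.

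Against early epiblast-like cells, the ESCs were higher for most primed genes and lower for most naive ones. The ESCs carry the title codes MS05 and MS11 and the early cells MS02, MS03 and MS08, so group and code cannot be told apart. SFRP1 rose by 8.17 ± 0.29 (SE, 3 cultures and 3 days), CCND2 by 7.39 ± 0.33 and FHL2, a LIM domain cofactor, by 6.79 ± 0.47. KHDC3L fell by 12.19 ± 0.23, DPPA5 by 10.96 ± 0.26 and DNMT3L by 8.74 ± 0.35. DPPA3, a maternal protein that protects DNA methylation, changed by -9.36 ± 0.30. Adjusted p was 2.61e-08 for SFRP1, 2.78e-10 for KHDC3L and 9.62e-10 for DPPA5. Of 10142 genes, 3031 passed the limma test, 1645 higher and 1386 lower in ESCs, and 4593 did not overlap, or 45.3% against 10% by chance. The naive list had 12 of 14 fall and 0 rise (12 and 1 adjusted over the list alone; camera adjusted p = 1.21e-11), and the primed list 14 of 15 rise and 0 fall (14 and 0 adjusted over the list alone; camera adjusted p = 2.62e-09). Trophectoderm markers had 4 of 5 fall, including KRT7 by 4.03 (camera adjusted p = 0.000158). These 3 lists had adjusted p = 0.0902 with an estimated correlation. Oxidative phosphorylation had 7 of 18 fall, including COX5A by 1.43 (camera adjusted p = 0.0046; adjusted p = 0.157 with an estimated correlation). Germ cell markers had 3 of 4 fall, including KIT by 2.25 (camera adjusted p = 0.0351; adjusted p = 0.311 with an estimated correlation). FGF and ERK signalling had 7 of 11 rise, including DUSP6 (4.54), FGF2 (4.34) and EGR1 (2.91), and FGF4 fell by 5.39 (camera adjusted p = 0.0662). NODAL fell by 4.30 and VIM rose by 6.06. With 1 culture left out the falls outnumbered the rises, with 758 higher and 1051 lower genes without CMK6 on feeder (1809 calls), 1021 and 1205 without the feeder-free culture and 942 and 1278 without CMK9. Without E07 there were 1338 and 835, without E08 1181 and 704 (1885 calls) and without E09 1371 and 749. In these fits a gene at the filter's level only in the group that lost a unit could not be tested. Genes tested were 9461 to 9689, beside 10142 in the main fit. The balance of rises and falls there thus follows in part from the filter.

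Trophectoderm-like cells were followed over E06 to E09. HAND1 and CDX2 rose by day, and AMOT, AQP3 and DPPA5 fell. The E06 cells lay in cluster 8, those of E07 in clusters 3 (10 cells) and 8 (9 cells) and those of E08 and E09 in cluster 3, so the trend follows a change of cluster. HAND1, a trophoblast and mesoderm transcription factor, rose by 2.25 ± 0.14 per day (SE, 4 days; adjusted p = 0.00061), from 2.79 at E06 through 4.67 and 7.64 to 9.28 at E09. CDX2, a transcription factor that specifies trophectoderm, rose by 1.07 ± 0.16 per day (adjusted p = 0.0421), and ID2, a BMP target, by 1.55 ± 0.23 (adjusted p = 0.0421). CD36, a fatty acid receptor, rose by 1.41 per day and the growth factor VEGFB by 1.22. PMP22 fell by 1.70 ± 0.21 per day, from 5.79 to 0.43, the Hippo pathway gene AMOT by 1.48, the water channel AQP3 by 1.23 and DPPA5 by 1.13 ± 0.15.

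The limma trend called 42 of 8819 genes, 24 rising and 18 falling. At an unadjusted p under 0.05 there were 1389, and 1190 genes changed one way at every step, or 13.5% against 8.33% by chance. BMP signalling had 2 of 8 members rise, ID2 and ID3 (0.96), and 0 fall (6 and 0 adjusted over the list alone; camera adjusted p = 2.66e-05; adjusted p = 0.366 with an estimated correlation). Trophectoderm markers had 1 of 8 rise, CDX2, and 0 fall (4 and 0 adjusted over the list alone; camera adjusted p = 0.000163; adjusted p = 0.366 with an estimated correlation). Trophoblast hormones and placental genes had 0 of 5 pass (3 rising adjusted over the list alone; camera adjusted p = 0.00236; adjusted p = 0.618 with an estimated correlation), with HSD3B1, an enzyme of steroid synthesis, at 2.02 per day and 3 higher genes at an unadjusted p under 0.05. WNT signalling had 0 of 4 pass (1 at an unadjusted p under 0.05; camera adjusted p = 0.0443; adjusted p = 0.618 with an estimated correlation). Camera placed oxidative phosphorylation (0 of 19 pass, 4 lower at an unadjusted p under 0.05; median -0.18 per day; adjusted p = 0.000238; adjusted p = 0.366 with an estimated correlation) below other genes. It did so too for the naive list (1 of 12 falls, DPPA5; adjusted p = 0.0196; adjusted p = 0.618 with an estimated correlation) and the core list (0 of 7 pass, 3 falling adjusted over the list alone; adjusted p = 0.0281; adjusted p = 0.618 with an estimated correlation). NANOG was at -1.23 per day (adjusted p = 0.054) and KLF4 at -1.59 without passing. No list member passed with edgeR. The count of calls is not stable: 1 without E06, 5 without E07, 320 without E08, 799 without E09, 1 after quantile normalization and 0 with edgeR, which gave 1257 genes at an unadjusted p under 0.05.

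Monkey ESC cultures were set beside each other without a test, since each is 1 sample. Without feeders, CMK6 was higher than on feeders for the WNT receptor FZD2 (4.74 ± 1.49, SD over cells, against 0.18 ± 0.36) and for the collagen COL2A1 by 3.78. It was lower for PLIN2, a lipid droplet protein (3.86 ± 1.53 against 8.06 ± 1.11), and for the stress genes SESN2 by 4.05 and TRIB3 by 3.93. All 10 core pluripotency members were lower without feeders (median -0.60, at percentile 0.02 of 10000 random lists matched on expression), with PRDM14, a germline and pluripotency regulator, at -2.29. Of 8 JAK-STAT and LIF genes 7 were lower (median -0.81, percentile 1.83), including IL6ST (-2.22) and STAT3 (-1.93). Dissociation stress genes were lower for 9 of 12 (median -0.87, percentile 0.02), with ATF3 at -2.88. The BMP list was higher for 6 of 9 (median 0.62, percentile 99), with ID3 at 1.54. The feeder-free cells carry the title code MS11 and those on feeders MS05, so culture and code cannot be told apart.

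CMK9 on feeder differed from CMK6 on feeder in the FGF and ERK list and in single genes. HMGA2, a chromatin protein, was at 7.72 ± 0.95 (SD over cells) against 2.75 ± 2.53, VIM at 9.01 ± 1.51 against 5.49 ± 2.28, and EOMES, a mesendoderm transcription factor, at 4.05 ± 2.99 against 0.42 ± 1.58. The adhesion gene CDH1 was lower by 2.17, as a difference of -2.17. The FGF and ERK list was higher for 6 of 10 genes (median 0.79, above all 10000 random lists), with DUSP6 at 3.38, ETV5 at 2.95 and EGR1 at -2.13. The adhesion list had a median of 0.43 (percentile 99.5), and dissociation stress genes had one of -0.71 (percentile 0.01).

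Across the 2000 most variable genes, all 3 ESC cultures had their highest Pearson correlation with epiblast-like cells of E17. The feeder-free culture had a correlation of 0.771 with E17, 0.718 with E16, 0.554 with E13 and 0.0320 with E08. CMK6 on feeder had 0.748 with E17 and 0.0836 with E08, and CMK9 0.648 and 0.0492. Genes are not independent replicates, and no p is given. The 2000 genes were chosen for their variance over these same days and cultures, so the low correlations with early days follow in part from that choice. With all tested genes, the highest correlations were 0.920, 0.917 and 0.884, all with E17. Those with E08 were 0.748, 0.771 and 0.746 in the same order of cultures.

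**Figure D3:**
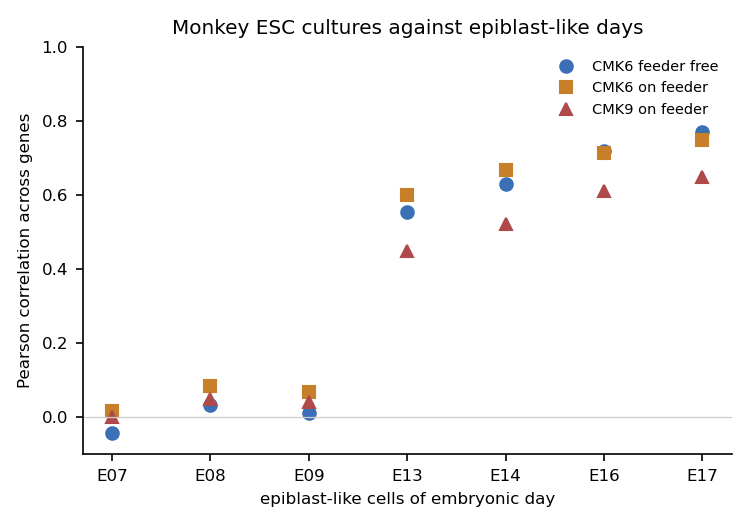
Pearson correlation across the 2000 most variable genes between each monkey ESC culture and the monkey epiblast-like cells of each embryonic day. In the monkey, the correlation with E17 was 0.771, 0.748 and 0.648 for the 3 cultures.

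Mouse ESCs, EpiLCs and embryo cells are 1 sample per group and were compared without a test, in their own table, since the monkey and mouse tables were normalized separately. ESCs and EpiLCs carry the title code MS61, E5.5 cells MS11 and E6.5 cells MS77, so in comparisons of embryo cells with cultures or between E5.5 and E6.5 the group and the code cannot be told apart. EpiLCs were higher than ESCs for Fgf5, a growth factor of postimplantation epiblast (6.49 ± 2.36, SD over cells, against 0.31 ± 0.30), and for the POU factor Pou3f1 by 6.00 and Otx2 by 5.09. They were lower for Klf4, a naive pluripotency factor (0.73 ± 0.48 against 7.36 ± 2.08), and had differences of -6.50 for Tfcp2l1, -6.39 for Esrrb and -4.35 for Nanog. Of 16 naive genes 14 were lower (median -3.33, below all 10000 random lists), and of 15 primed genes 14 were higher (median 2.07, above all of them). The FGF and ERK list was higher for 8 of 10 (median 1.28, percentile 99.97), with Dusp6 at 3.48, and the JAK-STAT and LIF list lower for 4 of 6 (median -2.28). Dnmt3a was higher by 4.01 and Dnmt3b by 2.85, but the median of the DNA methylation list was 0.84 and turned to -0.26 with the log of the mean RPM. Oxidative phosphorylation genes were lower for 17 of 19 (median -0.34, percentile 0.01).

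Epiblast-like cells of E5.5 differed from ESCs in the same direction as EpiLCs in the naive list (14 of 16 lower, median -3.54) and the primed list (15 of 16 higher, median 2.30). Both differences are taken from the same ESCs, so some likeness is to be expected, and it was not tested. Car4, a carbonic anhydrase, was higher than in ESCs by 7.62, Otx2 by 6.18 and Dnmt3l by 5.25, and Esrrb had a difference of -8.19 and Klf2 of -7.50. Against EpiLCs, E5.5 cells were higher for Dnmt3l (8.32 ± 0.84, SD over cells, against 3.91 ± 2.72) and for 8 of 9 DNA methylation genes (median 0.75, percentile 99.9). They were lower than EpiLCs for the NODAL inhibitors Lefty1 (-4.20) and Lefty2 (-3.33) and for 9 of 10 FGF and ERK genes (median -0.71, percentile 0.11). The correlation with E5.5 epiblast-like cells was 0.729 for EpiLCs and 0.410 for ESCs. The correlation with E6.5 was 0.599 and 0.187.

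Cells of E6.5 held transcripts known from B cells and from photoreceptors. The immunoglobulin light chain gene Igkc was found in 24 of 24 E6.5 cells, at 32.5 to 26053 RPM, and in 2 of the 47 other mouse cells, at up to 18.5 RPM. It exceeded 1000 RPM in 4 cells, of which 3 were epiblast-like and 1 visceral-endoderm-like. The cluster of E6.5 epiblast-like cells was led by Igkc, Ighm, Igl and Klf4, and had 5 of 9 epiblast markers elevated, Pou5f1, Nanog, Pou3f1, Tdgf1 and Utf1. The mouse markers included no B-cell class, so its leading B-cell genes did not count in the naming. Rbp3, a photoreceptor protein of the retina, was found in 24 of 24 E6.5 cells at 1.01 to 2289 RPM and in 0 of 47 others, and Pdc likewise at 0.668 to 1928 RPM. The E6.5 values below include these cells, and differences without the 4 cells with Igkc above 1000 RPM, a choice made after the values were seen, stand in brackets.

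**Figure D4:**
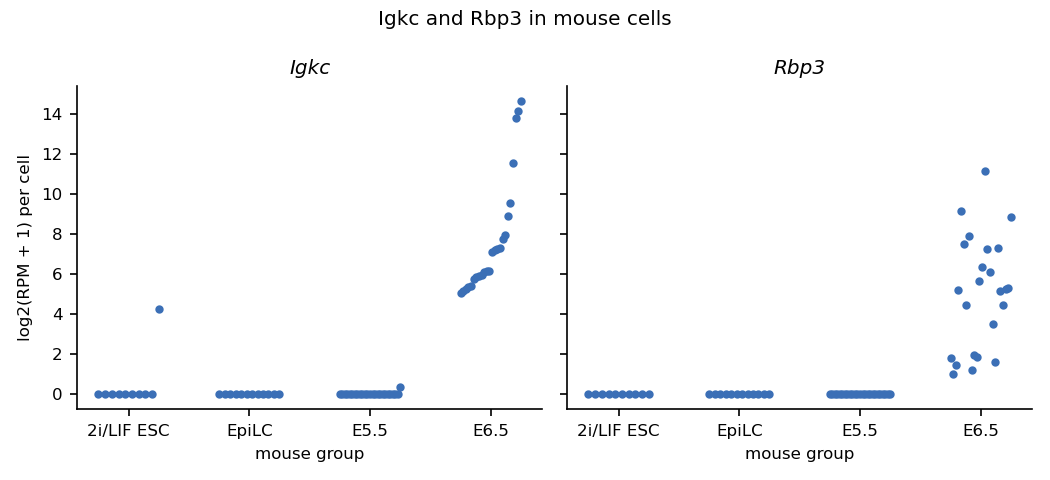
Igkc and Rbp3 (RPM + 1, log axes) in each mouse cell, by group. All 24 E6.5 cells lie above every other mouse cell for both genes.

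Epiblast-like cells of E6.5 were higher than those of E5.5 for Igkc by 9.27 (6.81 without the 4 cells) and for Ighm by 8.35 (5.79). The 16 E5.5 cells lay in mouse cluster 1 and the 9 E6.5 cells in cluster 4, so these differences follow a change of cluster. Klf4 was higher by 5.79 (5.75; 7.14 ± 0.84, SD over cells, against 1.35 ± 1.62), and Nanog by 2.60 (2.49). Klf4 was found in 23 of 24 E6.5 cells and in 37 of 47 other mouse cells, and it was also higher in E6.5 visceral-endoderm-like cells (below). Its rise was thus not particular to epiblast-like cells and was not separated from RNA of other cells. The difference was -5.72 (-4.66) for Dnmt3l, -5.43 (-5.56) for Dppa4 and -5.06 (-5.02) for Dppa2, both genes of pluripotent chromatin. The median over all genes was -0.53 and moved to -0.06 with the log of the mean RPM. Against it, the naive list was lower (6 of 8 members, median -3.20, -3.15 without the 4 cells, below all 10000 random lists) and glycolysis higher (13 of 16, median 0.38, 0.48 without them, percentile 99.9), with the glucose transporter Slc2a1 at 1.91 (2.15). Apolipoprotein and lipid transport genes were higher for 7 of 10 (median 1.55, 1.41 without them, percentile 99.95), led by Apoa4 at 4.30 (4.01) and Apoa1 at 3.37 (2.93). Both are also known from the small intestine, as is Fabp2, found in 24 of 24 E6.5 cells and in 3 of 47 other mouse cells, so this rise was not separated from RNA of other cells. The FGF feedback inhibitor Spry2 was higher by 3.21 (3.46). The labels give proximal parts as the source of E6.5 epiblast, so part and stage cannot be told apart.

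Visceral-endoderm-like cells of E6.5 were higher than those of E5.5 for Cer1, a NODAL and WNT inhibitor of anterior visceral endoderm (8.86 ± 2.09, SD over cells, against 2.50 ± 2.83; difference 6.37 without the 4 cells), and for Igfbp2 by 6.17 (6.42). Igkc was higher by 7.61 (6.62) and Klf4 by 5.74 (5.58). The 9 E5.5 cells lay in mouse cluster 3 and the 5 E6.5 cells in cluster 5, so these differences follow a change of cluster. The endocytic receptor Lrp2 was lower (3.31 ± 3.24 against 11.21 ± 0.63; difference -7.98 without them), and the water channel Aqp8 had a difference of -6.76 (-6.91). All 12 apolipoprotein and lipid transport genes were lower (median -1.80, -1.91 without them, below all 10000 random lists; median over all genes -0.62). Hypoblast and endoderm markers were lower for 13 of 15 (median -1.18, -1.19 without them, percentile 0.08), with Afp at 2.99 (2.90) and the receptor Cubn at -2.78 (-2.92).

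Changes in the monkey epiblast from early to late days and changes in the mouse were correlated across genes with the same symbol. Against mouse E6.5 epiblast-like cells minus ESCs, Pearson's r was 0.139 and Spearman's rho 0.137 over 6382 genes. Against EpiLCs minus ESCs they were 0.152 and 0.108 over 6439 genes, and against E6.5 minus E5.5 epiblast-like cells 0.0612 and 0.0954 over 6415 genes. Without the 4 cells with Igkc above 1000 RPM, r was 0.148 for the first and 0.0813 for the last.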

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

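Of the tests below, those of a stage difference in Igkc, that of other cells on the called falls and those on genes called without the cells tested were chosen only after the results were seen, and the alternatives with thinned reads and within MS11 were added after the data had been seen.

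Immunoglobulin RNA in mouse E6.5 cells stood apart from all other mouse cells, with 4 of 24 cells above 1000 RPM of Igkc. RNA of B cells is a candidate explanation for the 4 cells: 10 B-cell genes were higher there than in E5.5 cells by a median of 5.52 (log2), and the 8 without Cd52 and Cd79b, which had already led the cluster, by 5.32. Low-level carry-over into the other E6.5 libraries may account for the rest, since the 49 other genes highest in those cells were present in the remaining 20 cells at a median share of 0.864%, beside 0.943% for Igkc. Blood in general stays open: 9 genes of other blood cells were higher by a median of 0.80, Tyrobp by 3.29 and Cd3e and S100a9 by 0. A stage difference of epiblast cells alone is argued against, since 100% of the 15 E6.5 cells of other classes (lowest 32.5 RPM) had more Igkc than every mouse cell of the other groups (highest 18.5 RPM), but one joined by carry-over, which the 750-fold range of Igkc over the 9 epiblast-like cells does not exclude, or one of all E6.5 cells, whose title code no other group shares, stays open.

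For the difference between late and early epiblast-like days, chance is argued against but not excluded. Of the 35 splits of the 7 days, the real one gave 3752 genes and the highest other 475. Every other split mixes early and late days, which adds to the spread within groups, and days of 1 time course cannot be freely exchanged. Depth is argued against, since with each cell thinned to the same number of reads the median change of the called genes was 104% of that without thinning. Cells of the named classes compared are argued against for most genes and stay open for the rest. Of the called rises, 81.4% were at most 0.5 above the late epiblast-like cells in both extraembryonic-mesenchyme-like and gastrulating-like cells. Of the called falls, 74.5% were at most 0.5 above the early epiblast-like cells in both hypoblast-like or endoderm-like and trophectoderm-like cells. Late trophectoderm-like cells and those of the unnamed clusters were not compared, so they stay open. Title codes stay open: 96.1% of called genes had the same sign within the code MS08, but its cells helped to call them, and of 2075 genes called without its cells 94.6% had the same sign (median 1.68 beside 1.89), but the code holds only 2 early cells. The embryonic stage was not tested apart from dissection and embryo.

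For the difference between ESC cultures and late epiblast-like days, chance is argued against but not excluded. Of the 35 splits of the 7 units, the real one gave 888 genes and the highest other 8. Every other split mixes cultures and days, which adds to the spread within groups. Title codes stay open: 95.6% of called genes had the same sign within the code MS11, whose cells helped to call them, but of 595 genes called without its cells 80.7% did, with a median change of 0.74 beside 1.89. Of these, 78.6% of 486 rises and 89.9% of 109 falls kept their sign, while 58.1% of all tested genes were positive within the code. MS11 sets only 8 E17 cells against 9 feeder-free cells, so the smaller change cannot be assigned to code, day or feeders. RNA of feeder cells also stays open: the feeder-free culture's difference from the late days was 89.6% of the full one over the called rises, which that culture helped to call, but 55% over the 520 rises called from the cultures on feeders, of which 91% were higher in it than on the late days. For TAGLN it stood at 3.71, beside 7.65 and 9.15 on feeders, and culture was not tested apart from the cell line. Against early days, the 10 splits are too few for a share under 0.05, and the real split gave 3031 genes and the highest other 0.

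Of 68 groups of 4 to 10 samples tested for a value far from the others, 7 had one, and chance gives about 1 in 20. KHDC1L stood at 2.60 at E13 and at 0.54 to 0.70 on the other late days (gap over range 0.919). FAM240A and NLRP9 were at 0 on the late days except E16, at 0.08 and 0.03 (gap over range 1 for both), but with 3 of 4 values at 0 that gap is fixed and these 2 say nothing. TRIM60 stood at 2.04 at E17 and at 6.03 to 6.76 on the other late days (0.845). In feeder-free CMK6, 1 cell lay apart in recovered reads (1248431 to 3804305; 0.509) and 1 in genes detected (9954 to 12712; 0.507). In mouse ESCs 1 cell lay apart in genes detected (9297 to 10570; 0.669). Signals in cells outside the comparisons were the unnamed cluster 7, with 72.1% of E06 cells (56.3% to 84.7%), the unnamed cluster 9, with 21% of E14 cells (11.7% to 33.2%), and the unnamed mouse cluster 2, with 41.7% of E6.5 cells (22.1% to 63.4%).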

How the results depend on the processing

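The alternatives with thinned reads, with unnamed clusters counted as epiblast-like, within the title code MS11 and without E6.5 cells of high Igkc were chosen only after the data were seen. Of results for single genes and lists, 8959 comparisons with an alternative gave the same direction and side of the threshold, 730 were weaker, 206 stronger, 201 moved and 5 reversed. Counts, correlations and shares stayed within their limits in 179 comparisons and moved in 66. Values within 1 title code moved often: of ESCs against late days within MS11, 63 moved, 3 reversed and 35 stayed the same, of late against early epiblast within MS08 44, 1 and 60, and of the trophectoderm trend within MS03 4, 0 and 95. Reversed were MIXL1 in late against early epiblast with edgeR (0.24 against -2.20), GATA6 there within the title code MS08 (0.082 against -1.76) and, in ESCs against late days within MS11, TRIM60 (0.25 against -5.20), CRABP1 (-0.81 against 2.02) and HK2 (0.84 against -1.37); the cause was not tested.

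The 3752 genes of late against early epiblast were 763 with at least 10 cells per unit, which leaves 1 early day, and 2150 with the same number of cells per unit. Leaving out 1 day gave 2540 to 3681. Counting the unnamed E06 cluster as epiblast-like gave 4018 and the unnamed E13 and E14 cluster 3770. The 888 genes of ESCs against late days were 135 with no filter, 524 with the stricter filter, 456 with log2 of the mean RPM, 441 with quantile normalization, 13 with at least 10 cells per unit, which leaves 1 culture, 453 with the same number of cells and 364 with edgeR. Leaving out 1 unit gave 151 to 698. The 3031 genes of ESCs against early days were 1809 to 2226 with 1 unit left out. The 42 genes of the trophectoderm trend were 1 with a pseudocount of 10, 1 with the stricter filter, 1 with quantile normalization, 1 with thinned reads, 9 with units by title code and the day as a block, and 799 with at least 10 cells per unit, which leaves out E09. They were 0 with no filter, with log2 of the mean RPM, with the same number of cells, with edgeR and with limma without an intensity trend, where 2963, 1298, 1014, 1257 and 1274 genes had an unadjusted p under 0.05. Leaving out 1 day gave 1 to 799. Beyond that limit of the filter, the cause was not tested.

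Camera called 6 lists for late against early epiblast, 0 with an estimated correlation, 3 with the stricter filter and 3 to 7 with 1 day left out. It called 5 for ESCs against late days, 0 with an estimated correlation, 1 each with a pseudocount of 10, no filter, log2 of the mean RPM and quantile normalization, 3 with at least 10 cells, 2 with the same number of cells and 2 to 5 with 1 unit left out. It called 5 for ESCs against early days, 0 with an estimated correlation, 3 with the stricter filter and 5 to 8 with 1 unit left out. It called 7 for the trend, 0 with an estimated correlation, 3 with no filter and 6 to 7 with 1 day left out. The cause was not tested.

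Correlations between the 2 mouse profiles compared moved from 0.843 to 0.901 (pseudocount 10) and 0.933 (no filter) for EpiLC and ESC, from 0.818 to 0.880 and 0.926 for E5.5 and ESC, and from 0.915 to 0.966 (no filter) for E5.5 and EpiLC. They moved from 0.858 to 0.908, 0.935 and 0.807 (log2 of the mean RPM) for epiblast-like cells of E6.5 and E5.5, and from 0.811 to 0.869 and 0.912 for visceral-endoderm-like cells. With all tested genes in place of the most variable ones, the highest profile similarity was 0.920, 0.917 and 0.884 for CMK6 feeder-free, CMK6 on feeder and CMK9, 0.837 for mouse ESC and 0.924 for EpiLC. The epiblast-like share of E06 was 46.5% with the higher clustering resolution and 0 otherwise. The cause was not tested.

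No paired analysis was possible because the labels give no number that pairs a cell, embryo or animal of 1 group with one of another. The title codes MS08 and MS11, held by both groups of a comparison, would give 1 pair each, and MS03 holds E06, E07 and E09 of the trophectoderm trend. They were used for values only. Late against early endoderm-like cells was not run, since no late day held such cells. Among the epiblast-like units of the monkey, E13 had the lowest depth, a median of 852660 reads per cell.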

Other observations

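The test for photoreceptor RNA was chosen only after the result was seen, and the values by day below were not tested.

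Among the late epiblast-like days, values moved between E13 and E17. Of the naive list, DNMT3L stood at 6.53 at E13 and 0.33 at E17, DPPA3 at 6.84 and 1.27 and DPPA5 at 10.91 and 6.25, while ZFP42 was higher at E17 (4.92 and 5.85). Outside it, KHDC3L stood at 11.84 and 3.83, NLRP7 at 7.92 and 0.37 and OOEP at 7.21 and 0.75. The median of the naive list was 6.43, 6.41 and 7.22 at E07, E08 and E09, then 4.56, 3.58, 1.93 and 1.43 at E13, E14, E16 and E17. That of the primed list was 4.15 at E09, 6.04 at E13 and 7.22 at E17, beside 7.28 to 7.35 in the 3 ESC cultures.

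EOMES, BMP4 and some list medians also moved over these days. EOMES stood at 0.23 at E13, 0.42 at E14, 3.33 at E16 and 3.52 at E17, and BMP4 at 1.85, 2.27, 5.01 and 4.40. The median of the BMP list was 3.68 at E13, 5.54 at E16 and 4.54 at E17. The median of the oxidative phosphorylation list was 8.46 at E07 and 7.59 at E17, and that of dissociation stress genes 7.34 at E08 and 4.73 at E17. The E13 and E14 epiblast-like cells lay in cluster 4 and those of E16 and E17 in cluster 1, and each day is 1 unit.

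The E6.5 mouse cells also held RNA known from photoreceptors. Sag was found in 24 of 24 E6.5 cells and in 1 of 47 other mouse cells. RNA of photoreceptors in the E6.5 libraries is a hypothesis that was tested on 10 other photoreceptor genes: their median difference between E6.5 and the other mouse cells was 1.14 (log2), with Rom1, Cnga1 and Abca4 the highest. The cell with the highest Rbp3, Pdc, Crx and Sag had 149 RPM of Igkc, so the highest photoreceptor values did not lie in the cells with the highest Igkc. In the monkey, RBP3 and SAG were found in 6 of 421 cells each. Fabp2, known from the small intestine, was found in 24 of 24 E6.5 cells at 0.488 to 241 RPM and in 3 of 47 others.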
